A study of Anopheles gambiae with 56 samples.

How the data were processed

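Total RNA of staged eggs, aged in water at 25C and bleached before extraction, was labelled and hybridised to Affymetrix Plasmodium and Anopheles arrays, per the labels' protocols. The authors deposited log2 expression values estimated with RMA, a method that corrects background, normalizes arrays to each other and summarises the probes of a probe set, per the submitters' processing notes and design text; its version is not given in the sources used here. Such normalization brings arrays towards a common distribution, so a change of total RNA per egg cannot be seen, and changes near background are compressed. Scanner intensities were not used here.

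The table held 16167 mosquito probe sets. Of these, 42 had names of another form than the rest, and parasite and control probe sets were not analysed here. The detection filter chosen before the data were examined rested on parasite probe sets, so its preset substitute was used. The highest time point mean had to exceed the 30th percentile of all values, 5.40, which left 13495 probe sets. This percentile is called the detection threshold here. It was not set against a measured background, so a level below it is low but need not be background. A gene table of a current assembly (idAnoGambNW_F1_1) was searched by accession and matched 0 probe sets. The files do not pair probe sets with genes, so the preset gene lists and the preset rule for named genes, which took the 6 largest rises and falls per comparison among probe sets with an informative gene name, were not applied. In their place, the IDs with the largest changes are printed, at most 2 that rose and 2 that fell, a choice made after the values were seen. The text in an ID, such as X or 2R, is quoted as it stands.

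Arrays were grouped by the labelled hour. The values were fitted in R 4.3.3 with limma 3.58.1, with 1 coefficient per time point over all 56 arrays and empirical Bayes moderation (36 residual and 3.77 prior degrees of freedom). A call needed a Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of at least 1; tests were two-sided. In the F-test, the span of the means had to reach 1. The labels name the replicates as biological. Probe sets are not genes, and several can measure the same gene. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

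The procedure was tested on simulated data with the real means and spreads of 13495 probe sets, 200 of them changed from 8 h on. For the comparison of 8 h with 2 h, 38.0% of changes of 1 on the log2 scale were called, 86.0% of 1.5, 96.0% of 2 and 100% of 3, with 4 calls among 13295 unchanged probe sets. The simulated noise was independent between probe sets and arrays and had the same spread at all hours. The real arrays differ in these respects and in the number of changed probe sets, so these rates need not hold for them.

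Replicate numbers recur in all replicated time points. The correlation of deviations from the group means between arrays of the same number was 0.72, 0.24 and 0.50 for 8 h and 16 h, and 0.75, 0.19 and 0.35 for 16 h and 28.5 h, so those arrays were taken as paired on the data alone, with a threshold of 0.1 for each pair; the labels do not state a pairing. With the replicate block, 597 rose and 343 fell from 8 h to 16 h, and 700 rose and 435 fell from 16 h to 28.5 h. The alternatives tried were other filters, scalings, thresholds, probe set selections, time points, fits and left-out arrays; the closing section gives their effect. The position of each array along the course was estimated by interpolating between the means of the other arrays at steps of 0.1 h. An intensity trend with robust moderation changed 1 of 7471 calls in the 4 main comparisons.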

Results

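Gene expression was followed through embryogenesis of the malaria mosquito Anopheles gambiae (Kisumu strain) on Affymetrix arrays that carry probes for the mosquito and for the malaria parasite. The series held 56 arrays at 20 time points between 2 h and 52 h. There were 3 biological replicates at each of 18 time points, and 1 array each at 49 h and 52 h. Values were deposited on the log2 scale for 16167 mosquito probe sets, and 13495 of these rose above the detection threshold at 1 time point or more and were tested. Array medians lay between 6.18 and 6.43. The spread of values within an array tended to narrow with age. The lower and upper quartiles were 4.98 and 8.10 in 2 h replicate 1, and 5.35 and 7.56 in 46 h replicate 2. The cause of this narrowing was not tested, and it can bear on the balance of rises and falls. The files do not pair probe sets with genes, so groups of probe sets are described by their course, and very few are named by ID. Replicate arrays of a time point correlated across probe sets with r from 0.877 to 0.994, where probe sets are not independent replicates. The pooled replicate SD was lowest at 2 h (0.24 on the log2 scale, n = 3) and highest at 46 h (0.48, n = 3), with 0.45 at 28.5 h and 0.46 at 40 h. The number of arrays limits the precision of each value.

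The first question was which transcripts change at any time between laying and the end of embryogenesis. Most of the measured transcripts did. Of 13495 probe sets, 9681 passed the moderated F-test of limma (adjusted p under 0.05) with time point means that spanned at least 2-fold. The median span of these was 1.97 on the log2 scale. A span of at least 4-fold was reached by 4685, and of at least 8-fold by 2054. The course had an early and a late pole. The highest mean fell at 2 or 4 h in 3869 of the 9681 (40.0%) and at 43 or 46 h in 1619 (16.7%), whereas 552 (5.70%) were highest between 19 and 25 h. The lowest mean fell at 43 or 46 h in 3442 and at 2 or 4 h in 2571. At the late pole 43 h prevailed: 1320 were highest there against 299 at 46 h, and 2575 were lowest there against 867. The first principal component held 55.6% of the variance and the second 16.5%.

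The change from 2 h to 8 h was taken as the passage from RNA laid down in the egg to transcription by the embryo. At least 2-fold changes were called in 1737 probe sets that fell and 1328 that rose (limma, adjusted p under 0.05). Under quantile normalization the split was nearly even, with 1407 falls and 1363 rises. It was wider when arrays were aligned on the probe sets not tested, with 1845 falls and 1261 rises. The rises were the larger in size, with 246 of at least 8-fold against 104 falls of that size. The probe sets that fell had a median level of 8.41 ± 0.06 at 2 h (SD of the array medians, n = 3), 7.71 ± 0.27 at 4 h and 6.80 ± 0.05 at 6 h. They stayed near that level afterwards, with 6.50 ± 0.09 at 46 h. Those that rose started at 5.74 ± 0.02 at 2 h, reached 7.86 ± 0.08 at 6 h and 8.36 ± 0.14 at 10 h, and stood at 7.87 ± 0.31 at 46 h. Of the 1328, 528 (39.8%) had a 2 h mean below the detection threshold, so their fold change is measured from a low level that may be near background. The largest rise was that of Ag.2R.4674.0_at, from 3.62 ± 0.27 to 12.30 ± 0.36 (SD, n = 3), a log2 difference of 8.68 ± 0.40 (SE) with a limma adjusted p of 7.6e-20; its 2 h mean too lay below the threshold. The largest fall was that of Ag.3R.2622.0_at, from 11.59 ± 0.41 to 6.03 ± 0.73, where the log2 level fell by 5.56 ± 0.54 (SE) with a limma adjusted p of 2.6e-11. With 4 h in place of 2 h, 976 probe sets fell by 8 h.

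The interval from 8 h to 16 h covers the time in which the serosa, an extraembryonic layer, encloses the embryo and secretes a cuticle, a structure studied for its part in the egg's tolerance of drying. At 16 h, 551 probe sets were higher than at 8 h and 318 were lower (limma, adjusted p under 0.05, at least 2-fold). With no minimum fold the balance turned, to 920 rises and 936 falls. The median difference over all tested probe sets was -0.04. The median rise was 1.51 on the log2 scale, and 65 probe sets rose at least 8-fold. Of the 551, 120 (21.8%) had an 8 h mean below the detection threshold. Both counts depended on the time points chosen, with 364 rises and 194 falls from 8 h to 13 h, and 220 rises and 158 falls from 10 h to 16 h. From 8 h to 19 h, 484 fell. The counts also moved with single 8 h arrays. Without 8 h replicate 2, placed at 6.5 h along the course of the other arrays, 426 rose and 269 fell. Without 8 h replicate 1, 626 rose and 335 fell.

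A smaller group was high in that window compared with the times before and after it. The mean over 10, 13 and 16 h exceeded both the mean over 2, 4 and 6 h and the mean over 25, 28.5 and 31 h by at least 2-fold in 145 probe sets (1.07% of those tested), and was lower than both in 48. The median level of the 145 rose from 5.30 ± 0.05 at 2 h (SD of the array medians, n = 3) through 7.32 ± 0.54 at 8 h to 8.61 ± 0.12 at 10 h and 8.57 ± 0.12 at 13 h. It was 7.95 ± 0.09 at 16 h and 6.33 ± 0.32 at 31 h. Of the 145, 46 were highest at 10 h, 40 at 13 h and 19 at 16 h. The others were highest outside the window: 2 at 6 h, 7 at 7 h, 8 at 8 h and 23 at still other times. The sharpest course was that of Ag.X.80.0_UTR_a_at, which stood at 5.31 ± 0.22 at 8 h, 12.34 ± 0.58 at 10 h, 12.96 ± 0.20 at 13 h and 6.78 ± 1.07 at 31 h (SD, n = 3). It was higher again at 46 h, at 10.27 ± 0.42. It also had the largest rise from 8 h to 16 h, 7.36 ± 0.60 (SE), and the largest fall from 16 h to 28.5 h, in which the log2 level fell by 5.24 ± 0.60 (SE), with limma adjusted p of 2.8e-12 and 1.1e-08. Both SEs rest on the spread over all time points. The 28.5 h arrays of this probe set spread more widely, at 7.43 ± 1.92 (SD, n = 3), so the fall is less precise than its SE. The 8 h mean of Ag.X.80.0_UTR_a_at lay below the detection threshold of 5.40, so the rise is measured from a level that may be near background. Ag.X.80.0_CDS_a_at, with the same ID number, lay above that threshold at 8 h and rose less, from 6.73 ± 0.05 to 12.24 ± 0.32 at 16 h (SD, n = 3).

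**Figure D1:**
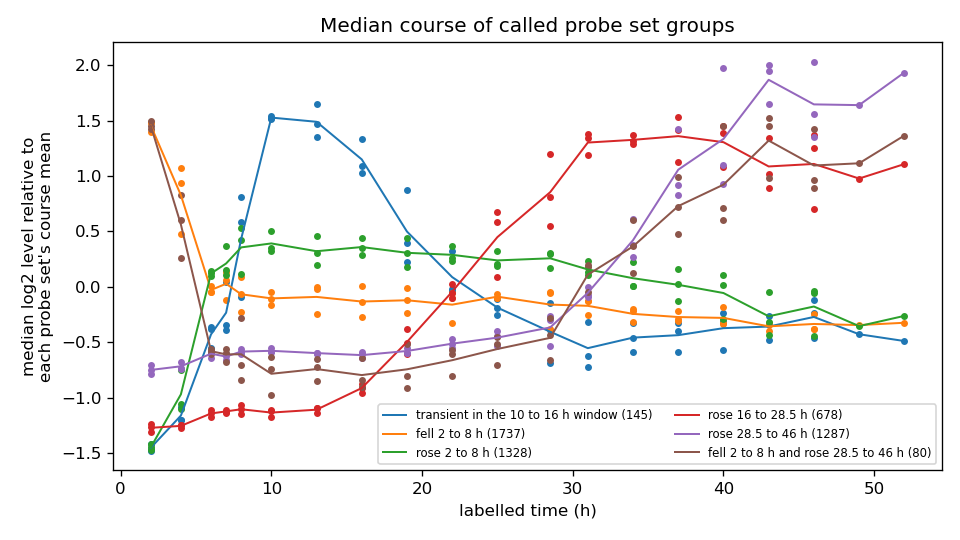
Median log2 level of 6 groups of called probe sets, relative to the mean of each probe set over the course, against the labelled time in h; each point is 1 array, lines join time point means, and the legend gives the number of probe sets. The 145 probe sets of the 10 to 16 h window are high at 10 and 13 h, and the 1287 that rose from 28.5 h to 46 h climb after 28.5 h. At 49 h and 52 h there is 1 array each. The groups were chosen on these arrays, so their shape is partly set by that choice.

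From 16 h to 28.5 h, the middle of embryogenesis, 678 probe sets rose and 422 fell (limma, adjusted p under 0.05, at least 2-fold). Rises were again the larger, with 95 of at least 8-fold against 10 falls of that size. Of the 678, 268 (39.5%) had a 16 h mean below the detection threshold. The probe sets that rose went up gradually, from 5.70 ± 0.05 at 16 h (SD of the array medians, n = 3) to 6.70 ± 0.10 at 22 h and 7.72 ± 0.40 at 28.5 h, and stood at 8.23 ± 0.08 at 31 h. The 28.5 h arrays differed more from each other than most, and counts moved with the neighbouring time point, to 445 rises and 245 falls at 25 h and to 1114 rises and 758 falls at 31 h. With the 16 h and 28.5 h arrays alone in the fit, 434 rose and 330 fell without the replicate block, and 627 rose and 427 fell with it. From 19 h to 28.5 h, 444 rose and 225 fell.

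Late embryogenesis, from 28.5 h to 46 h, brought large rises in a part of the transcripts. There were 1287 probe sets that rose and 1150 that fell (limma, adjusted p under 0.05, at least 2-fold). Of the rises, 296 were of at least 8-fold, against 9 falls of that size. The largest rise was 9.18 on the log2 scale, from a 28.5 h mean of 4.35 that lay below the detection threshold. The probe sets that rose had a median level of 5.75 ± 0.22 at 28.5 h (SD of the array medians, n = 3), 6.76 ± 0.15 at 34 h, 7.44 ± 0.35 at 37 h and 8.27 ± 0.17 at 43 h. Of the 1287, 490 (38.1%) had a 28.5 h mean below the detection threshold. The median difference over all tested probe sets was -0.16, and was -0.22 when arrays were aligned on the probe sets below the detection threshold. Whether rises or falls were the more numerous depended on the setting. There were 1196 rises and 1372 falls under that alignment, but 1370 rises and 1013 falls under quantile normalization. With no minimum fold, 2385 rose and 3527 fell. With 43 h in place of 46 h, 1463 rose and 1607 fell. The count of falls was 740 without 46 h replicate 2, 1586 at the highest when leaving out other single arrays, 703 with only these time points in the fit, and 486 from 31 h to 46 h. The count of rises was also lower with only these time points in the fit, at 860, and at 938 with the replicate block added. Leaving out 28.5 h replicate 1, 40 h replicate 2 and 46 h replicate 3, arrays that stood apart from their groups, gave 1427 rises and 2025 falls. At 46 h, replicate 2 stood apart too: it correlated less with replicate 1 (r = 0.940) than replicate 3 did (r = 0.951). Leaving out 46 h replicate 3 alone gave 1385 rises and 1482 falls, and leaving out 46 h replicate 2 alone gave 1100 and 740.

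The overlap of calls was counted between comparisons that share no arrays, beside the number that independent lists would share. Of the 1328 that rose from 2 h to 8 h, 308 fell from 28.5 h to 46 h, where 113.2 would be expected of independent lists. Of the 551 that rose from 8 h to 16 h, 130 fell from 28.5 h to 46 h, against 47.0 expected. The 1737 that fell from 2 h to 8 h held 80 that rose from 28.5 h to 46 h, below the 165.7 expected, and likewise 80 that fell in that interval, below the 148.0 expected. Of the 318 that fell from 8 h to 16 h, 60 rose from 28.5 h to 46 h, against 30.3 expected. These expected numbers take no account of level. The 1150 that fell from 28.5 h to 46 h had a median of 8.43 at 28.5 h. The 1328 stood near it at that hour, at 8.31 ± 0.07, whereas the median over all tested probe sets was 6.76 at 34 h. Level can thus account for part of these differences, and no draw matched on level was made for them. The 80 that fell early and rose late had a median level of 9.42 ± 0.09 at 2 h, 6.84 ± 0.31 at 8 h and 8.78 ± 0.41 at 46 h (SD of the array medians, n = 3).

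Neighbouring time points were compared to see when expression changed fastest. The 17 steps between replicated time points gave 3487 calls in sum (limma, adjusted p under 0.05, at least 2-fold). The step from 4 h to 6 h had 1609, or 804.5 per hour, with 679 rises and 930 falls, and the step from 2 h to 4 h had 744. From 8 h to 10 h there were 240, and the number declined to 21 from 19 h to 22 h. From 28.5 h on, calls were nearly all rises: 166 of 169 from 28.5 h to 31 h, 157 of 158 from 31 h to 34 h, 96 of 96 from 34 h to 37 h and 141 of 141 from 40 h to 43 h. Over the whole interval from 28.5 h to 46 h, however, 1150 probe sets fell and 1287 rose. The lack of falls in single steps thus does not show that late levels only rose. In 4 steps limma called 0 probe sets, with 287 at an unadjusted p under 0.05 from 6 h to 7 h, 514 from 22 h to 25 h, 231 from 37 h to 40 h and 550 from 43 h to 46 h. In 10 of the 17 steps the replicate numbers paired the arrays by the correlation of their deviations, the step from 37 h to 40 h among them. With the replicate block the steps gave 3814 calls in sum, and the same 4 steps again had 0 by limma, with 631, 804, 358 and 920 at an unadjusted p under 0.05. With the block and only the arrays of the step in the fit, limma called 6 probe sets from 37 h to 40 h, all rises, 134 in place of 50 from 16 h to 19 h, 78 in place of 21 from 19 h to 22 h, and 15 in place of 169 from 28.5 h to 31 h. From 7 h to 8 h, that fit called 0 in place of 73 (1312 at an unadjusted p under 0.05). Those steps met the pairing rule. Among the steps that did not, the same fit called 69 in place of 158 from 31 h to 34 h, 0 in place of 96 from 34 h to 37 h (723 at an unadjusted p under 0.05) and 0 in place of 141 from 40 h to 43 h (1273 at that level). Steps differ in length and replicate spread, so a low count there does not show that expression stood still.

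**Figure D2:**
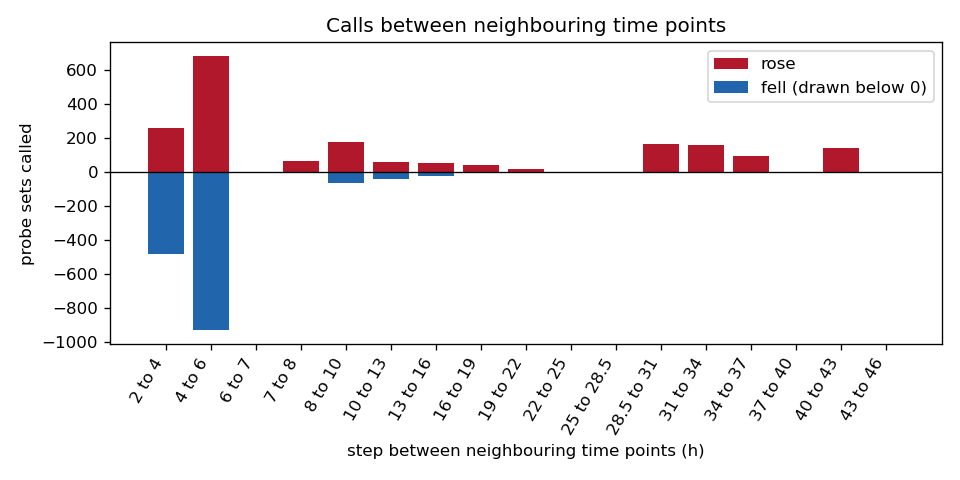
Number of probe sets called between neighbouring time points (limma, adjusted p under 0.05, at least 2-fold), with rises drawn above 0 and falls below, against the step in h. The step from 4 h to 6 h has 679 rises and 930 falls, and the steps after 28.5 h hold almost only rises. Over the whole interval from 28.5 h to 46 h, 1150 probe sets fell and 1287 rose.

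At the end of embryogenesis, the single arrays at 49 h and 52 h were set against the 3 arrays at 46 h. The number of differences depended strongly on the fit. In the fit without a block, 9 rose and 8 fell (limma, adjusted p under 0.05, at least 2-fold), and 1119 had an unadjusted p under 0.05. The lone arrays are assumed to vary like the replicated time points. Both carry replicate number 1, so a block on that number treats them like the other arrays of that number, a link the labels do not state. With the replicate number as a block the count of 17 became 321, without the 3 arrays that stood apart 255, and under quantile normalization 42. It also moved with each 46 h array. It was 207 without replicate 3, 3 without replicate 1 and 9 without replicate 2, and was 1 with the 49 h array alone, 6 with the 52 h array alone and 1 against 43 h.

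Probe sets whose ID carries X changed less often over the course than those whose ID carries 2L, 2R, 3L or 3R. Of 1221 tested X probe sets, 712 (58.3%) were called in the course, against 8534 of 11522 (74.1%) for those 4 labels together, which ranged from 73.7% to 74.3%. The share of X lay below the 71.1% to 75.2% (central range) found in 1000 random draws of their probe sets matched on mean level. Probe sets whose ID carries UNKN had a share of 58.1%. The median span was 1.23 on the log2 scale for X and 1.64 for the others.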

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

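Most alternatives were chosen before the data were examined. Those chosen afterwards included the stricter filter, the alignment on probe sets not tested and 1 probe set per ID number. The others were the fit of 2 time points with the block, and leaving out 28.5 h replicate 1, 40 h replicate 2 and 46 h replicate 3. Of 241 alternative values of 12 counts, 203 were within 1.5 times the reported count, 18 were higher and 20 lower. The planned filter and alignment on parasite probe sets were not run, since those probe sets were not analysed here. The alignment on ribosomal protein probe sets, 1 probe set per gene and all gene list alternatives were not run, since they need a pairing of probe sets with genes. Near background, signal limits what can be measured.

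With no minimum fold, 2531 rose and 3316 fell from 2 h to 8 h, 920 and 936 from 8 h to 16 h, 1201 and 1103 from 16 h to 28.5 h, and 2385 and 3527 from 28.5 h to 46 h; the window set had 807 and the steps 7740. These are larger because the fold limit was dropped. With other time points, 976 fell from 4 h to 8 h; 364 rose and 194 fell from 8 h to 13 h; 484 fell from 8 h to 19 h; 220 rose and 158 fell from 10 h to 16 h; 445 rose and 245 fell from 16 h to 25 h; 1114 rose and 758 fell from 16 h to 31 h; 444 rose and 225 fell from 19 h to 28.5 h; 486 fell from 31 h to 46 h. With only the compared time points in the fit, 434 rose from 16 h to 28.5 h and 703 fell from 28.5 h to 46 h. With the block added these were 627 and 820. Over all arrays, 678 rose from 16 h to 28.5 h without the block and 700 with it. The low count of 434 thus arose only where the fit was limited to these time points and also held no block. Without the 3 arrays named above, 2025 fell from 28.5 h to 46 h; the cause was not tested.

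The 17 calls of 49 and 52 h against 46 h became 42 under quantile normalization, 11 without _s_at and _x_at probe sets, 8 at adjusted p under 0.01, 255 without the 3 arrays, 1 with 49 h alone, 6 with 52 h alone and 1 against 43 h. With the replicate block there were 321; the block moved no other count past 1.5 times. The same-number correlation was 0.40, 0.02 and 0.17 for 2 h and 8 h and 0.38, -0.06 and 0.33 for 28.5 h and 46 h, where the arrays share only a number; the block gave 1345 rises and 1757 falls, and 1295 and 1206.

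Leaving out 1 array at a time gave 1248 to 1396 rises and 1643 to 1849 falls from 2 h to 8 h, 426 to 626 and 269 to 351 from 8 h to 16 h, 526 to 770 and 326 to 506 from 16 h to 28.5 h, and 1100 to 1385 and 740 to 1586 from 28.5 h to 46 h, where 740 was without 46 h replicate 2. The last comparison gave 3 to 207: 3 without 46 h replicate 1, 9 without replicate 2 and 207 without replicate 3. Leaving out each replicate number gave 8804 to 10021 for the course, 148 to 156 for the window set and 2805 to 3118 for the steps.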

Other observations

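The counts of other splits of the arrays were planned before their results were seen. The other tests of explanations in this part were chosen after the patterns had been seen, and 1 criterion, the margin in the exchange test, was added after its value was known.

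Probe sets with the same ID number and different regions give a check within the arrays. Of 634 pairs of a CDS and a UTR probe set, 479 had both members called in the course, and the median correlation of their time point means was 0.968, against 0.02 for random pairs. In 14 of the 479 the correlation was below 0. Summed over the 4 main comparisons, where a pair can count more than once, both members were called in the same direction 305 times and in opposite directions 4 times, all 4 from 2 h to 8 h.

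Along the course of the other arrays, 19 of 54 arrays lay within 1 h of their label and 45 within 3 h. The median absolute difference was 1.6 h. Steps between replicated time points were 1 h to 3.5 h long, so 3 h is a wide margin. The farthest were 43 h replicate 3 at 52.0 h, the end of the range searched, 46 h replicate 3 at 38.1 h, 28.5 h replicate 1 at 23.4 h and 46 h replicate 1 at 41.4 h. All 46 h arrays were placed before their label, with replicate 2 at 43.0 h. The 43 h arrays were placed at 43.0 h or later, so the order of 43 h and 46 h along the course is uncertain. The arrays weighed here, 40 h replicate 2 (at 43.0 h) and 46 h replicate 3, were picked because they correlated best with arrays of other time points; moving them along the course removed 78.6% and 83.6% of their squared distance from the labelled hour, against a median of 28.8% and a highest value of 74.7% in the other 52 arrays. Since that choice already places them elsewhere on the course, the shares decide neither for embryos older or younger than labelled nor against poor RNA or hybridisation, and both stay open. An exchange of the 2 arrays stays open too: it lowered the pooled SD from 0.46 to 0.30 at 40 h and from 0.48 to 0.40 at 46 h, and the higher of these, 0.399, exceeded the highest neighbouring value, 0.389, a difference that would have excluded the exchange under the criterion first written and no longer does with the margin added later, the spread of the neighbours. No biological explanation was tested, and labels were kept as given.

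The lower share of changing probe sets with X in the ID was set against 3 technical explanations. Draws from probe sets with 2L, 2R, 3L or 3R in the ID, matched on mean level, had 71.1% to 75.2% called (central range of 1000 draws), above the 58.3% of X, which argues against lower signal. Without _s_at and _x_at probe sets the shares were 57.8% and 74.1%, which argues against shared probes, and the median replicate SD was lower on X, 0.246 against 0.269, which argues against larger noise. A compressed response of X probe sets, which could lower both span and SD, stays open, and probe sets with UNKN in the ID had a share of 58.1%. No biological explanation was tested, since the design has no group for it.

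Some probe sets of the 10 to 16 h window rose again late. From 34 h to 46 h, arrays that do not enter the definition of the window set, 28 of 145 rose (19.3%) and 2 fell, against 4.55% rises over all tested probe sets. Random sets gave 1.38% to 8.28%, and sets matched on the 34 h level 2.07% to 8.97%, below the 19.3% in both cases. This argues against a low level at 34 h as the only reason. Neither kind of draw was matched on the span over the course, and the window set was chosen for large differences. The excess can therefore follow from that choice, and a larger swing of these probe sets in general stays open. This is a minority: the median difference of the 145 was 0.0016. The position of 46 h replicate 3 along the course stays open, and no biological explanation was tested.

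In the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real split had 3065 calls from 2 h to 8 h (highest other split 2), 869 from 8 h to 16 h (3), 1100 from 16 h to 28.5 h (94) and 2437 from 28.5 h to 46 h (1326); in each, 1 of the 10 splits, the real one, gave as many. Among 100 regroupings of 54 arrays, the real one included, 1 gave as many as the 9681 calls of the course (highest other 7610) and 1 as many as the 145 of the window set (highest other 0), so hours assigned to arrays at random can be excluded for these. Since regrouping mixes distant hours within a group and widens its spread, this does not test the window against another order of the course. For the 3487 calls of the steps, 4 gave as many, with 19526 the highest other. Random labels set distant times side by side, so this count points to the structure of the course and says little about the steps themselves.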
